A study of Mus musculus with 29 samples.

How the data were processed

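RNA of brain and ovary metastases of a Braf-mutated mouse melanoma model was extracted with AllPrep and mirVana kits and turned into T cell receptor libraries with the QIAseq Immune Repertoire RNA kit, per the labels' protocols. The authors deposited 1 combined table of whole-number counts, with a column per sample and 49519 combinations of chain, V segment, J segment and CDR3 amino acid sequence. The counts carry no normalization. Whether a count is a read or a molecule is not stated, and the aligner, the clonotype caller and its filters are not given in the sources used here. The submitters' processing notes name the genome build GRCh38, which is a human build, for this mouse study, so no coordinates are given. Mouse segment names were looked up in the RefSeq table of GRCm38.p6, where 25 of 25 single TRBV names and 67 of 67 single TRAV names matched.

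The table used here lists 27517 TRB and 22002 TRA combinations. The labels also name gamma and delta chains, of which the table used here holds none, so the planned family of 16 brain tests became 12. Of 609329 counts, 0.0364% had a CDR3 with an unresolved residue and were left out of the measures. The table joins names where a sequence could not be assigned to a single V segment (81 of 173 V names, nearly all TRAV, whose segments are duplicated in the mouse), and such names were kept as written. PCR copies would make counts less independent than molecules, so intervals cover counting error only.

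Groups were taken from the treatment label and the organ in the sample title. Titles also give a number and a part, and the labels do not say what either stands for. Values of the parts of a number were averaged, which gave 2 numbers per brain treatment. Per sample, the measures were log2 of the TRB count, log2 of the expected number of TRB clonotypes in 266 counts (the lowest brain total), and the unbiased Simpson concentration of TRB clonotypes. In the ovary, richness was also computed at 16179 counts, and comparisons between organs used 266. Diversity values required 100 counts. On simulated repertoires of 2000 clonotypes with independent counts, the mean concentration over simulations deviated from the true value by 1.31% at 300 counts and 0.221% at 3000. This measures the bias of the mean and not the spread of single samples. Secondary measures were the share of the 10 largest TRB clonotypes, the shares of TRAV11 or TRAV11D with TRAJ18 and of TRAV1 with TRAJ33 among TRA counts, mean TRB CDR3 length and the number of TRB clonotypes holding 1% or more. Joined names that hold TRAV11 or TRAV11D were counted for the first pair, whatever other segments they name. At these depths a count of 0 allows a share of up to 3 counts of the total.

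Brain tests were exact permutation tests over numbers: the sum of squares between 5 treatments, the lead-in and any anti-PD-L1 permuted within day, and trametinib against none. Overlap was the Morisita-Horn index, tested one-sided by exact permutation of the matching of parts or organs. All other tests were two-sided. Adjustment was by Benjamini-Hochberg within each family, with a threshold of 0.05. V segment counts, summed over the parts of a number, were tested with edgeR 4.0.16 (quasi-likelihood, offset by the log chain total, all 10 brain libraries in 1 fit, segments with at least 10 counts in at least 2 libraries) in R 4.3.3, with DESeq2 1.42.0 as an alternative. Other measures were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.

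Which items to name was fixed before the data were examined: V segments past the threshold, the segments of the invariant natural killer T and mucosal-associated invariant T lists, the range over TRBV segments, the TRB clonotype of highest mean share in each group and the 3 of highest share in each organ. No V segment passed in the planned fits, so the other segments named are those with low p-values or with calls under an alternative, chosen with their largest clonotypes after their values were seen. The planned definition of invariant natural killer T chains named TRAV11 and TRAV11D. TRAV11N was added as an alternative after the data had been seen, since most TRAJ18 counts of the family carry that name.

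Same-numbered brain and ovary samples were checked for pairing. Deviations of V segment usage from the organ means correlated across 110 segments at 0.372, 0.207, 0.237, 0.601 and 0.303 for numbers 1, 3, 10, 12 and 13, all above 0.1, so the numbers were taken to pair the organs. The highest correlation of unmatched numbers, brain number 1 with ovary number 10, was 0.125 and also above 0.1. Segments are not independent replicates. Intervals of Morisita's index between parts came from 1000 resamples of the counts, and were widened by the square root of the chi-square per degree of freedom after a first look had shown that the parts differed by more than independent counts would. No pair of sample columns was identical.

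The tests were tried on simulated data. Counts drawn for the lead-in combination against the concurrent combination, with 20 of 99 segments changed 8-fold among those below 1% of their chain, gave 21.3% of the changed segments back at a false call share of 0.696%, and 4-fold changes gave 2.5%. For brain against ovary with 111 segments the shares were 70.8% at 8-fold, with 0.714% false calls, and 26.5% at 4-fold. The restriction to small segments was set after simulations with changes in segments of any size, in which 4-fold changes gave 7.5% and 45% of the changed segments back in the brain and organ comparisons, with 0.253% and 1.10% false calls, and 16-fold changes gave 74.5% and 94.75% back, with false calls in 11.6% and 25.1% of the unchanged segments. A change in a large segment also shifts the shares of the other segments of its chain, so calls beside a dominant segment have to be read with this error. Most changes of 8-fold or less in small segments would go uncalled in brain. The permutation test called 3.8% of 500 simulated unchanged data sets at a p under 0.05.

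Alternatives comprised clonotypes by CDR3 alone, without single counts, with unresolved residues, a minimum of 500 counts, rarefaction to 100 counts, Shannon clonality, ranks, the TRA chain, parts pooled or taken as samples, TMM or no filter for V segments, distinct clonotypes in place of counts, the number as a block, and leaving out each sample or number. Samples and numbers with no partner in the other organ entered brain comparisons only.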

Results

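T cell receptor transcripts were counted in brain and ovary metastases of a Braf-mutated mouse melanoma model, in 29 samples. The series title asks whether giving an antibody against PD-L1 before a MAPK inhibitor combination is of benefit. PD-L1 is the ligand of the T cell checkpoint receptor PD-1, and trametinib inhibits the MAPK pathway kinase MEK. The 5 treatments were untreated (day 0, given as no treatment in the labels and as vehicle in the titles), anti-PD-L1 lead-in (day 0), trametinib (day 3), trametinib with anti-PD-L1 (day 3, the concurrent combination) and lead-in followed by trametinib with anti-PD-L1 (day 3, the lead-in combination). The 19 brain samples held 3 untreated samples and 4 of each other treatment, and the 10 ovary samples held 2 of each treatment. Each sample title carries a number, and all but 1 brain sample also carry part 1 or part 2 of that number. Each brain treatment had 2 numbers and each ovary treatment had 1, with 5 numbers sampled in both organs.

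A clonotype was a V segment, a J segment and a CDR3 amino acid sequence, the CDR3 being the part of the receptor that contacts antigen most variably. Brain samples held 266 to 7067 beta chain (TRB) counts and 230 to 9389 alpha chain (TRA) counts. Ovary samples held 16179 to 51674 TRB counts and 14088 to 51549 TRA counts. Most TRB clonotypes were private: 26581 occurred in 1 number, 645 in 2 numbers, and the most widely shared was found in 9 of 10 numbers. The labels do not say whether a number is an animal or what a part is, so p-values measure the spread between numbers or samples only. Intervals given for single samples are exact Clopper-Pearson 95% intervals and, like the limits given for a count of 0, cover counting error only.

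Brain metastases of the lead-in combination held the most T cell receptor transcripts. Mean TRB counts per sample were 5882 ± 1235 (SD, n = 4) in the lead-in combination, 1849 ± 902 (n = 4) in the concurrent combination, 1882 ± 2327 (n = 4) in the lead-in alone, 551 ± 148 (n = 4) in trametinib and 409 ± 170 (n = 3) in untreated samples. All 4 samples of the lead-in combination (4148 to 7067) lay above the other day 3 samples, the highest of which was 3195. The lead-in samples of day 0 (266 to 5317) overlapped the untreated ones (302 to 605), and the highest of them was part 1 of number 11. Amounts of input RNA are not known, so these totals are an unscaled yield.

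The comparison across treatments was made on log2 TRB counts averaged over the parts of each number, with exact permutation tests over 10 numbers. Samples with a lead-in were 2.06 log2 units higher within day (exact two-sided permutation p = 0.0333, adjusted p = 0.178 over 12 tests). For every measure, the day 3 samples without a lead-in were those of trametinib and of the concurrent combination together. The lead-in contrast is therefore not separate from anti-PD-L1. On day 0 both contrasts compare the lead-in alone with untreated samples. Samples with any anti-PD-L1 were 2.04 log2 units higher within day (exact p = 0.0444, adjusted p = 0.178). Those with trametinib were 1.37 log2 units higher than those without (exact p = 0.195, adjusted p = 0.335). The 5 treatments took up 80.8% of the sum of squares (exact p = 0.0698, adjusted p = 0.210). None passed the adjusted threshold of 0.05. The smallest exact p was 0.0111 for the within-day tests, 0.00476 for trametinib and 0.00106 for the 5 treatments. With each part counted as its own sample, adjusted p was 0.00572 for the lead-in, for anti-PD-L1 and for the 5 treatments, but parts of a number share clonotypes, so those p-values are too small. Over all alternatives the adjusted p of the lead-in and of anti-PD-L1 ran from 0.00572 to 0.4 (exact or resampled permutation tests), and that of the 5 treatments from 0.00572 to 0.437. Trametinib was given only in day 3 samples, so treatment and day cannot be told apart in that contrast.

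The beta chain repertoire was on average most concentrated in the lead-in combination. The Simpson concentration, the chance that a pair of counts belongs to the same clonotype, was 1.83% ± 0.69 (SD, n = 4) there, 0.759% ± 0.531 (n = 4) in the concurrent combination, 0.812% ± 0.457 (n = 4) in the lead-in alone, 0.696% ± 0.166 (n = 4) in trametinib and 0.698% ± 0.221 (n = 3) in untreated samples. Samples of the lead-in combination had 1.07% to 2.70%, overlapping the concurrent combination (highest 1.49%) and the lead-in alone (highest 1.43%). The 10 largest clonotypes held 29.5% ± 3.9 of TRB counts in the lead-in combination and means of 17.9% to 19.6% in the other treatments. Clonotype richness in 266 drawn counts was 161 ± 12 in the lead-in combination, 187 ± 20 in the concurrent combination, 143 ± 47 in the lead-in alone, 146 ± 18 in trametinib and 140 ± 21 in untreated samples.

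Over the 10 numbers, concentration was 0.73 percentage points higher with a lead-in within day (exact two-sided permutation p = 0.0222, adjusted p = 0.178), 0.43 points higher with anti-PD-L1 (exact p = 0.311, adjusted p = 0.467) and 0.37 points higher with trametinib (exact p = 0.390, adjusted p = 0.521). The 5 treatments took up 67.8% of its sum of squares (exact p = 0.12, adjusted p = 0.287). Log2 richness differed by -0.06 with the lead-in (exact p = 0.700, adjusted p = 0.700), 0.12 with anti-PD-L1 (exact p = 0.5, adjusted p = 0.545) and 0.22 with trametinib (exact p = 0.186, adjusted p = 0.335), and the treatments took up 46.4% of its sum of squares (exact p = 0.449, adjusted p = 0.538). None passed. Without number 14 the concentration differences were 0.404 points for the lead-in, 0.216 for anti-PD-L1 and 0.12 for trametinib, and with other samples or numbers left out they reached 0.977, 0.577 and 0.51. The richness differences ran from -0.16 to 0.065, 0.015 to 0.27 and 0.12 to 0.34, with both ends of each set by leaving out number 10 or a part of it. The share of the richness sum of squares taken up by the 5 treatments ran from 28.4% to 75.5% with a sample or number left out. Counting each part as its own sample gave adjusted p = 0.0147 for concentration with the lead-in and 0.0363 for the 5 treatments. The sign of the richness difference with the lead-in turned when clonotypes of a single count were left out (0.17), when parts were pooled (0.06) or at a minimum of 500 counts (0.05).

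**Figure D1:**
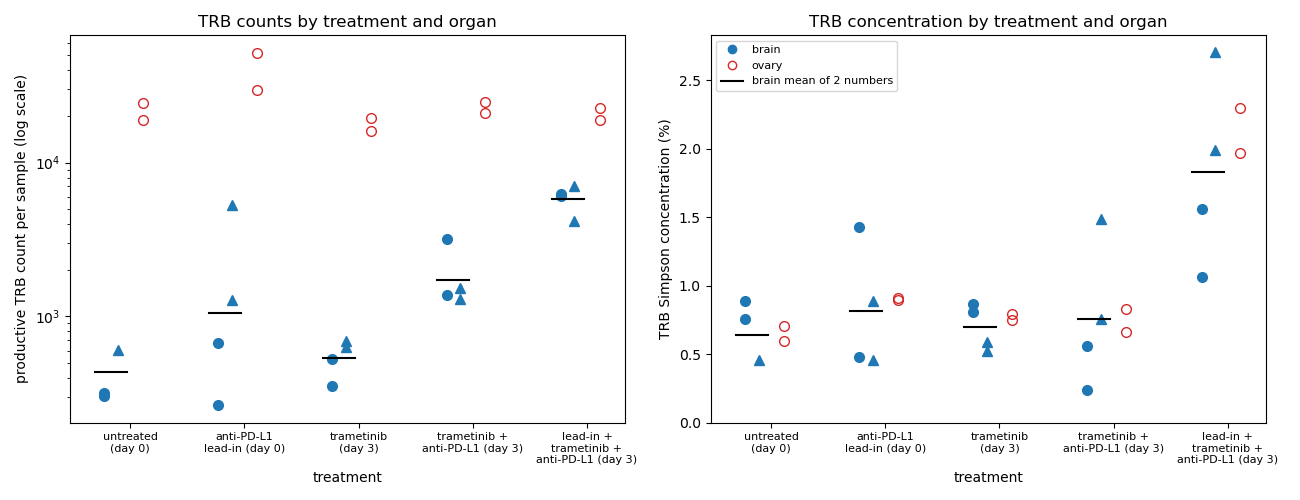
TRB counts per sample on a log axis (left) and TRB Simpson concentration in percent (right) by treatment, with filled blue symbols for brain samples, circles and triangles marking the 2 brain numbers of a treatment, open red circles for ovary samples and black lines for the mean of the 2 brain numbers (of log2 counts on the left). Brain samples of the lead-in combination held 4148 to 7067 counts, above the other day 3 brain samples, and ovary samples held at least 16179.

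The lead-in combination and the concurrent combination differ only in the lead-in. Brain TRB counts were 12.50 ± 0.33 against 10.75 ± 0.60 log2 units (SD, n = 4 and 4), a difference of 1.75 log2 units or 3.36-fold. All 4 lead-in samples lay above all 4 concurrent ones (exact two-sided permutation p = 0.0286, the smallest that 70 assignments allow, adjusted p = 0.0571 over 3 measures). Simpson concentration was 1.07 percentage points higher with the lead-in (exact permutation p = 0.0571, adjusted p = 0.0571), and log2 richness differed by -0.22 (exact permutation p = 0.0571, adjusted p = 0.0571). With a sample or number left out, the concentration difference ran from 0.555 points (without number 14) to 1.59 and the richness difference from -0.33 (without number 6) to -0.10 (without number 1). Alpha chain concentration was 6.20% and 3.53% in the parts of number 12 and 1.16% and 2.58% in those of number 14, against 0.533% to 0.967% in the concurrent samples. On that chain the counts differed by 1.80 log2 units and the concentration by 2.61 percentage points, each passing at adjusted p = 0.0429 (exact permutation test). Over all alternatives the adjusted p ran from there to 0.2 for counts and 0.333 for concentration. Samples of a number share clonotypes, so these p-values over samples are too small, and an exact test over numbers, 2 against 2, cannot go below p = 0.333.

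Innate-like T cells were followed through their invariant alpha chains. Invariant natural killer T cells, which recognise lipids on CD1d, carry TRAV11 joined to TRAJ18, and in brain this pair held 2.15% ± 2.14 (SD, n = 3) of TRA counts in untreated samples, 0.0627% ± 0.1253 (n = 4) in the lead-in alone, 0.295% ± 0.409 (n = 4) in trametinib, 0.267% ± 0.195 (n = 4) in the concurrent and 0.171% ± 0.164 (n = 4) in the lead-in combination. The duplicated segment TRAV11N carried most TRAJ18 rearrangements of the family, and with it counted the shares were 6.46% ± 4.65, 0.968% ± 1.009, 3.47% ± 0.74, 1.25% ± 0.60 and 0.847% ± 0.350, in the same order. Mucosal-associated invariant T cells, which recognise microbial vitamin B metabolites on MR1, carry TRAV1 joined to TRAJ33. That pair was found in only 1 of 19 brain samples, with 3 counts, and held up to 26 counts in an ovary sample. Mean TRB CDR3 length lay between 13.6 and 14.3 residues in brain samples.

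None of the 20 tests on these secondary measures passed, the lowest p being that of the share of the 10 largest clonotypes with the lead-in, 7.64 percentage points higher within day (exact two-sided permutation p = 0.0667, adjusted p = 0.578). The invariant natural killer T share differed by -0.70 percentage points with the lead-in (exact p = 0.167, adjusted p = 0.578), -0.68 with anti-PD-L1 (exact p = 0.267, adjusted p = 0.578) and -0.61 with trametinib (exact p = 0.443, adjusted p = 0.578). By this definition they rested on untreated number 3, without which they were -0.105, -0.082 and 0.150 points, and without number 7 the first 2 were -1.10 and -1.08. With TRAV11N counted, a definition chosen after the data were seen, the differences were -2.57 points with the lead-in (exact p = 0.0778, adjusted p = 0.519), -3.11 with anti-PD-L1 (exact p = 0.0222, adjusted p = 0.444) and -1.19 with trametinib (exact p = 0.652, adjusted p = 0.815). On day 3 the trametinib samples then held 2.67% to 4.42%, above the 0.412% to 1.72% of the concurrent and 0.458% to 1.31% of the lead-in combination. Without number 3 these differences were -1.05, -1.66 and 0.844 points, and without number 7 -3.73, -4.34 and -1.83, so their size rested on the untreated numbers by this definition too. Over all alternatives the adjusted p ran from 0.191 to 0.857 for the lead-in, 0.191 to 0.944 for anti-PD-L1 and 0.231 to 1 for trametinib (exact or resampled permutation tests). CDR3 length differed by 0.15 residues with the lead-in (exact p = 0.200, adjusted p = 0.578) and by 0.071 without number 14. The number of clonotypes holding 1% or more differed by -1.28 with the lead-in (exact p = 0.856, adjusted p = 1), and by -4.58 without number 10 to 1.83 without its part 2. In untreated brain the TRAV11 share was 4.41% (95% interval 2.54% to 7.06%) and 1.89% (0.764% to 3.86%) in the parts of number 3 and 0.157% (0.00399% to 0.874%, 1 count) in number 7.

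Ovary metastases of the lead-in combination also had the most concentrated repertoire, with 1 number per treatment and hence no test. They came from number 12, whose brain samples are among those above and overlapped with them by 52.4% (Morisita-Horn index). The ovary of the lead-in combination is therefore not independent of the brain result. In this ovary the TRB Simpson concentration was 2.13% ± 0.23 (SD of 2 parts), against means of 0.652% to 0.903% in the other treatments, and its 10 largest TRB clonotypes held 36.1% ± 0.5 of counts. Its TRA concentration was 9.81% ± 0.34, against 0.851% to 2.86%. Its TRB counts, 20787 ± 2699, lay within the range of the other treatments, 17815 ± 2313 in trametinib to 40595 ± 15668 in the lead-in alone. Invariant natural killer T alpha chains by the planned definition (TRAV11 with TRAJ18) held 1.44% ± 0.34 of TRA counts in the trametinib ovary and 0.241% to 0.617% in the others. With TRAV11N counted, these shares were 6.98% ± 0.92 and 1.59% to 3.93%.

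Ovary metastases held more T cell receptor transcripts than brain metastases of the same numbers. TRB counts were 14.51 ± 0.43 log2 units in ovary and 10 ± 1.79 in brain (SD, n = 5 numbers each), 22.9-fold higher and higher in 5 of 5 numbers (exact two-sided permutation p = 0.00794, the smallest this design allows, adjusted p = 0.0238 over 3 measures). Paired by number, the exact sign-flip test gave p = 0.0625, the smallest it can give with 5 pairs, and adjusted p = 0.188. With any 1 number left out the unpaired exact test gave p = 0.0286, the smallest it can then give, and adjusted p = 0.0857. Richness at equal depth differed by 0.19 log2 units (exact permutation p = 0.294, adjusted p = 0.440) and concentration by 0.23 percentage points (exact permutation p = 0.579, adjusted p = 0.579), neither passing. Without number 12 these were 0.30 and 0.0855, and without number 3 the first was 0.096. Organ and library preparation cannot be told apart, since the library indices of the labels run separately in each organ.

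Within brain, V segment usage was compared in 10 libraries (parts of a number summed) with edgeR's quasi-likelihood test over 99 segments. In the lead-in combination against the concurrent combination, TRAV7D-2 held 26.3% ± 6.6 against 12.9% ± 2.2 of TRA counts (SD, n = 2 numbers each, log2 difference 1.03 ± 0.32 SE, edgeR adjusted p = 0.389, the lowest of the comparison). TRBV23 held 4.76% ± 6.52 against 0.379% ± 0.164 of TRB counts (log2 difference 3.66 ± 1.43, edgeR adjusted p = 0.680), with 9.37% in number 12 and 0.152% in number 14. TRBV29 held 16.7% in number 14 and 3.83% in number 12. TRBV4 held 1.63% ± 0.17 against 5.15% ± 4.37, with 8.24% in number 6 of the concurrent combination.

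No segment passed in this comparison, with 5 of 99 at an unadjusted edgeR p under 0.05 and 0 past the threshold by DESeq2. TRAV7D-2 passed with no filter on low counts (adjusted p = 0.00380) and with each part as its own library (adjusted p = 0.0265). Without number 14 it was called together with TRBV23 (edgeR adjusted p = 0.0291 for each), but number 12 was then the only library of the lead-in combination and its spread was taken from the other groups. In number 12 a single clonotype, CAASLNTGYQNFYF (TRAJ49), held 20.6% of the TRA counts, and TRAV7D-2 held 31.0% with it and 13.2% of the remaining counts without it. In number 14 TRAV7D-2 held 21.6%, and 16.1% without its largest clonotype, against 11.3% and 14.4% in the concurrent combination (7.95% and 10.2% without the largest). Of the 9.37% of TRBV23 in number 12, 8.02% was 1 clonotype. Against the lead-in alone, TRAV7D-2 held 26.3% ± 6.6 against 13.3% ± 3.7 (log2 difference 0.98 ± 0.32, edgeR adjusted p = 0.515) and TRBV16 4.90% ± 0.04 against 9.96% ± 1.57 (-1.03 ± 0.37, adjusted p = 0.515). No segment passed there by edgeR or DESeq2, with 4 at an unadjusted p under 0.05, and TRAV7D-2 passed with no filter (adjusted p = 0.00942).

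In the other brain comparisons no segment passed by edgeR or by DESeq2, with 5 of 99 at an unadjusted edgeR p under 0.05 in each. For lead-in against untreated, TRAV11/TRAV11D held 0.105% ± 0.149 against 1.44% ± 1.82 of TRA counts (log2 difference -3.34 ± 1.48, edgeR adjusted p = 0.816). The untreated mean came from number 3 (2.73%), and number 7 (0.157%) lay between lead-in numbers 10 (0 counts among 930, which allows up to 0.323%) and 11 (0.211%). For trametinib against untreated, TRBV17 held 6.62% ± 3.16 against 2.44% ± 0.18 (1.43 ± 0.56, adjusted p = 0.626). For the concurrent combination against trametinib, TRAV2 held 0.0168% ± 0.0237 against 0.654% ± 0.184 (-4.93 ± 1.55, adjusted p = 0.489) and TRBV19 8.78% ± 0.12 against 13% ± 1.2 (-0.57 ± 0.38, adjusted p = 0.845). Without number 7, TRAV6-6/TRAV6D-6 was called in lead-in against untreated (edgeR adjusted p = 0.0293), where number 3, with 0 counts of it among 733, was the only untreated library and its spread was taken from the other groups. Number 7 held 2.99%, within the range of the lead-in numbers (1.57% and 3.98%).

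Segments of the invariant natural killer T list (TRAV11/TRAV11D with TRBV13-2, TRBV29 and TRBV1, the beta segments those cells use) were lower in 4 of 4 cases for lead-in against untreated and for trametinib against untreated, 2 of 4 for the concurrent combination against trametinib and for the lead-in combination against the lead-in alone, and 3 of 4 for the lead-in against the concurrent combination. TRBV13-2 held 6.61% ± 1.17 in the lead-in combination and 9.80% ± 1.14 in the concurrent one, and TRBV1 6.16% ± 1.48 in the lead-in alone and 10.2% ± 0.1 in untreated brain (n = 2 numbers each). Of the mucosal-associated invariant T list (TRAV1, TRBV13-2, TRBV13-3 and TRBV19), TRBV19 held 9.16% ± 2.67 and 8.78% ± 0.12 in the lead-in and concurrent combinations. By edgeR 0 of 4 members of either list passed in any comparison, and 0 passed when adjusted over the list alone, the lowest such adjusted p in brain being 0.146. At an unadjusted p under 0.05 only TRAV11/TRAV11D in lead-in against untreated stood among them in brain. Of 21 TRBV segments tested in brain, log2 differences ranged from -0.72 (TRBV1) to 1.11 (TRBV20) for lead-in against untreated, -0.98 (TRBV30) to 1.43 (TRBV17) for trametinib against untreated, -1.12 (TRBV23) to 1.69 (TRBV4) for the concurrent combination against trametinib, -1.65 (TRBV4) to 3.66 (TRBV23) for the lead-in against the concurrent combination and -1.19 (TRBV30) to 1.83 (TRBV23) against the lead-in alone. Adjusted over the TRBV list alone, 0 passed in each.

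Between organs, TRBV19 held 10.8% ± 2.7 of TRB counts in brain and 6.55% ± 1.07 in ovary (SD, n = 5 numbers each, log2 difference 0.72 ± 0.26 SE, edgeR adjusted p = 0.186), and TRBV29 held 6.45% ± 1.57 and 3.89% ± 0.33 (0.73 ± 0.28, edgeR adjusted p = 0.202). The lowest edgeR p values belonged to alpha segments whose reads the table could not assign to a single copy, such as TRAV7-2/TRAV7D-2 with 0.342% ± 0.274 in brain and 0.0447% ± 0.0126 in ovary (2.78 ± 0.74, adjusted p = 0.0919). Such joined names held 37.9% ± 6.7 of brain and 30.3% ± 7.3 of ovary TRA counts, higher in brain in 5 of 5 numbers (exact two-sided paired permutation p = 0.0625, the smallest 5 pairs allow). Of 111 segments 0 passed by edgeR, with 15 at an unadjusted p under 0.05, 13 of them higher in brain. With the number as a block 0 passed and 20 had an unadjusted p under 0.05, while DESeq2 called 6 and edgeR with each part as its own library called 9. All DESeq2 calls were joined names. The calls with each part as its own library were joined names, TRAV7-3, TRBV19 and TRBV29. Among 23 TRBV segments the log2 difference of brain against ovary ran from -2.66 (TRBV21) to 0.73 (TRBV23), and 0 passed adjusted over the list alone. Of the invariant natural killer T and mucosal-associated invariant T lists 0 of 4 members each passed in the edgeR fit of summed parts, the lowest p adjusted over the list alone being 0.0537. With each part as its own library, TRBV29 of the first list and TRBV19 of the second were called. Parts of a number share clonotypes, so those calls are too easily made.

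Metastases that shared a number shared beta chain clonotypes. Brain and ovary of the same number overlapped by 22.5% to 52.4% (Morisita-Horn index), with a mean of 38.9% over 5 numbers, against a mean of 0.682% and a highest value of 3.12% for unmatched numbers (exact one-sided permutation p = 0.00833, the smallest that 120 matchings allow). The parts of a brain number overlapped by 40.8% on average, against 0.235% for parts of different numbers of the same treatment (exact one-sided permutation p = 0.0123, the smallest that 81 pairings allow, n = 8 numbers). Overlap of parts in brain was 91.5% in number 12 and 92.0% in number 14 of the lead-in combination, 52.4% and 3.83% in the lead-in alone (numbers 11 and 10), 32.4% and 13.6% in the concurrent combination (numbers 1 and 6), 25.5% and 15.6% in trametinib (numbers 13 and 8) and 7.63% in untreated number 3. In ovary it was 55.9% to 87.4%. The chi-square between parts was 4.06 to 20.02 per degree of freedom in 9 brain and 5 ovary numbers. It takes counts as independent, and copies of 1 molecule would raise it, so it does not settle whether the parts are libraries of the same RNA.

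**Figure D2:**
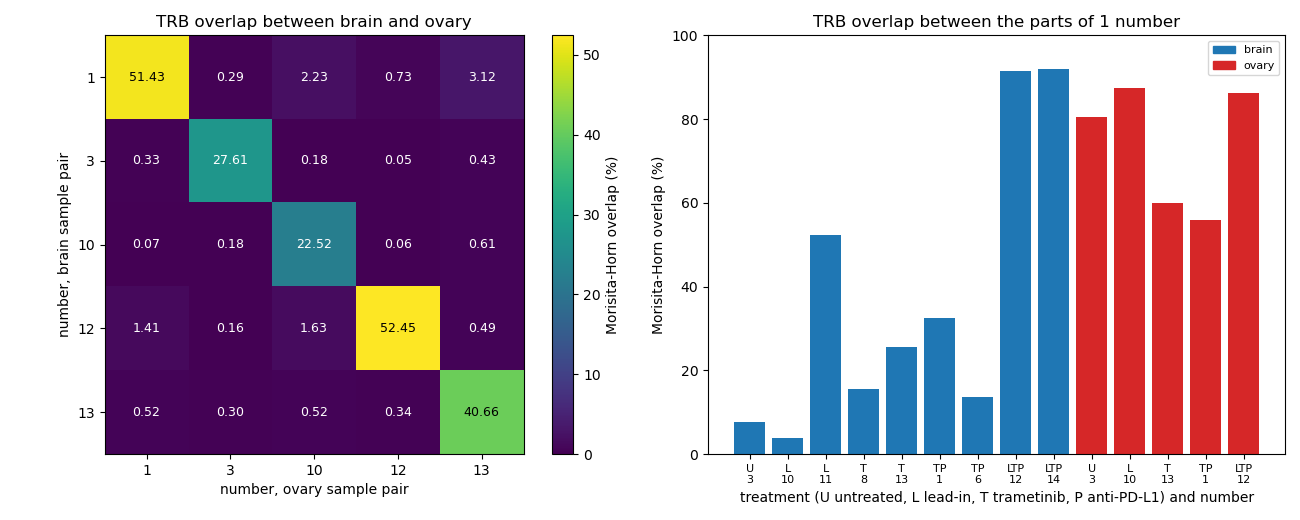
Morisita-Horn overlap of TRB clonotypes in percent between brain (vertical axis) and ovary (horizontal axis) of the 5 numbers sampled in both organs (left), and between the 2 parts of each number (right; blue bars brain, red bars ovary). Matched organs overlapped by 22.5% or more and unmatched ones by 3.12% or less; 1 value stands behind each bar, so there are no error bars.

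Most of the expanded ovary clonotypes were also found in the brain of their number. Of the ovary clonotypes holding 1% or more, the brain of the same number contained 11 of 11 in number 1, 5 of 8 in number 3, 9 of 14 in number 10, 15 of 16 in number 12 and 10 of 10 in number 13. At the shares they had in ovary, 8 of 8 were expected in the brain of number 3, 14 of 14 in number 10 and 16 of 16 in number 12, if counts are independent. Clonotypes holding 1% or more in both organs numbered 1, 0, 1, 5 and 3 in the same order. In number 12 the TRBV23 clonotype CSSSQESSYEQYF (TRBJ2-7) held 8.83% (95% interval 8.12% to 9.57%) and 7.23% (6.60% to 7.90%) of the brain parts and 4.45% (4.18% to 4.72%) and 6.42% (6.07% to 6.78%) of the ovary parts. The leading ovary clonotype of that number, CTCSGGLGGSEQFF (TRBV1, TRBJ2-1), held 9.92% ± 1.40 in ovary (SD of 2 parts) and 0.132% (0.0569% to 0.259%) and 0.385% (0.247% to 0.572%) in its brain parts. In number 14 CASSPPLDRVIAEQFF (TRBV29, TRBJ2-1) held 11.8% (11.03% to 12.5%) and 14.3% (13.3% to 15.4%) of brain TRB counts.

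The leading clonotypes of the other groups were smaller or unevenly spread over parts. In the concurrent combination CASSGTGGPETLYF (TRBV4, TRBJ2-3) held 10.2% (8.57% to 11.9%) of part 1 and 0.0655% (0.00166% to 0.364%) of part 2 of brain number 6. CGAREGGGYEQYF (TRBV20, TRBJ2-7) held 2.69% (2.27% to 3.16%) and 4.08% (3.07% to 5.32%) in lead-in number 11, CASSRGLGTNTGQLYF (TRBV17, TRBJ2-2) 4.17% (2.63% to 6.25%) and 1.69% (0.624% to 3.65%) in trametinib number 8, and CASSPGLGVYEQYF (TRBV16, TRBJ2-7) 0.331% (0.00838% to 1.83%) and 3.44% (1.73% to 6.07%) in untreated number 3. The last was also found in lead-in brain number 11, at 0.940% (0.699% to 1.24%) and 0.707% (0.324% to 1.34%). In ovary the leading clonotypes were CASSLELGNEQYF (TRBV16, TRBJ2-7) with 5.67% ± 0.25 in the lead-in alone, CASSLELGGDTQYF (TRBV16, TRBJ2-5) with 4.51% ± 1.20 in untreated, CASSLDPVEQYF (TRBV12-1, TRBJ2-7) with 3.65% ± 3.96 in trametinib and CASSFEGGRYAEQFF (TRBV3, TRBJ2-1) with 3.17% ± 1.22 in the concurrent combination (SD of 2 parts each). All 4 were also found in brain samples of their own number, at 0.0939% (0.0194% to 0.274%) to 1.56% (0.509% to 3.61%) of the parts that held them.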

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

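Of the tests in this part, the depth test and the comparison of the lead-in combination with the other numbers for the match of brain parts were chosen after the result was seen. All 3 patterns weighed here were noticed in the data.

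A sample far from the rest was looked for in 29 sets of 4 brain samples (a measure in a treatment), and 3 stood out, where chance gives about 1 in 20. Part 1 of lead-in brain number 11 held a TRAV11 with TRAJ18 share of 0.251% (95% interval 0.146% to 0.401%), where the other 3 lead-in brain samples held 0. The same sample held a TRAV1 with TRAJ33 share of 0.0442% (0.00912% to 0.129%, 3 counts), where the others held 0. With 0 in the other 3 samples, any count at all would stand out by this rule. The rate of 1 in 20 therefore does not apply to these items, both from the same sample. That sample had 6782 TRA counts, and the others had 230, 700 and 1292, in which a count of 0 allows shares of up to 1.30%, 0.429% and 0.232%. Part 1 of lead-in brain number 10, with 266 TRB counts, had 43 clonotypes holding 1% or more, against 8 to 12 in the other 3 samples; at that depth 3 counts reach 1%. In data left out of the comparisons, CDR3s with an unresolved residue held 0.0592% (0.0419% to 0.0812%) of counts in the trametinib ovary and 0.0273% (0.0181% to 0.0395%) in the untreated ovary.

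The parts of both brain numbers of the lead-in combination matched closely, at 91.5% and 92.0%. Morisita's index, which does not fall with depth if counts are independent, reached at most 56.1% (resampled 95% interval 42.8% to 69.8%) among the other 7 numbers. The parts differed by more than independent counts would, so the index need not be free of depth here. Lower depth of the other numbers therefore stays open. A few large clonotypes do not account for all of it, since number 14, the lower of both lead-in combination numbers, still had 57.3% (48.0% to 67.2%) without the 10 largest clonotypes of each number, above the highest other number at 35.8% (27.5% to 43.9%), after 92.8% (87.7% to 96.9%) with them. The 2 lead-in combination numbers ranked highest of 9 (exact two-sided permutation p = 0.0278, 2 against 7, the smallest the design gives), but this restates how the pattern was noticed and supports no treatment explanation. How parts were taken is not stated, and ovary parts reached 87.4% in the lead-in alone and 80.4% in untreated tissue, so the treatment and other explanations stay open.

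Brain and ovary of a number shared TRB clonotypes. Carry-over spread over libraries whatever their number is argued against. The 10 largest ovary clonotypes of each number held at least 26.4-fold more of the brain counts of their own number than of other numbers. In number 12 this was at least 1677-fold, against a floor of 3 counts over the other brain samples. The ratio largely restates the low overlap between unmatched numbers. Carry-over between brain and ovary material of the same number would give such ratios too and was not tested. T cell clones present in both organs of an animal may be the source, if a number is an animal, which the labels do not state; blood left in the tissues was not tested.

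The TRA clonotype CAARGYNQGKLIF (TRAV7D-2, TRAJ23) was found in 27 of 29 samples with 12223 counts. Carry-over between libraries is argued against by the other 20 largest TRA clonotypes, which were found in a median of 4 samples (range 2 to 29), 1 of them with more counts. Frequent independent recombination stays open. The 7 TRA CDR3s found in 20 or more samples occurred with a median of 11 V segment names (13 for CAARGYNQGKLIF), against 1 for 202 CDR3s of at least 100 counts found in 1 number, but a CDR3 found in more samples and with more counts has more chances to collect V names, misassigned ones included, so this comparison decides nothing. No biological explanation from the design was tested.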

How the results depend on the processing

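Alternatives chosen after the data were seen were the TRAV11N definition (also with each number left out), the TRA chain and left-out numbers for overlap, and the alternatives of the organ measures other than the paired test. The cause of each change below was not tested unless stated. Depth limits the brain most, where samples start at 266 TRB counts.

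With each part as its own sample, the 5 treatments took up 73.8% of the sum of squares of TRB counts and the differences were 2.16 log2 units for the lead-in and 2.14 for anti-PD-L1, and for concentration 54.8% and 0.738 percentage points, all 5 then passing; this setting has 19 values for 10 numbers, so its p-values are too small. On the TRA chain the lead-in against the concurrent combination passed for counts (1.80 log2 units) and concentration (2.61 points). That concentration was higher in the parts of number 12 (6.20% and 3.53%) than in those of number 14 (1.16% and 2.58%). Adjusted p over the alternatives ran from 0.0147 to 0.4 for concentration with the lead-in.

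The richness difference with the lead-in turned to 0.17 without clonotypes of count 1, 0.053 at a minimum of 500 counts and 0.064 with parts pooled, and ranged from -0.16 to 0.065 when a sample or number was left out. The richness difference with anti-PD-L1 turned to -0.0066 at rarefaction to 100. The number of clonotypes of 1% or more turned to 0.75 for trametinib with parts pooled and 0.25 for the lead-in on ranks, the latter ranging from -4.58 to 1.83 with samples left out. The invariant natural killer T share with trametinib turned to 0.417 on ranks and 0.844 with TRAV11N and without number 3, and ranged from -0.928 to 0.150 with samples left out, the highest without number 3. The TRAV1 with TRAJ33 share, seen in 1 brain sample, ranged from 0 to 0.00885 points for the lead-in and for anti-PD-L1 and from -0.0111 to 0 for trametinib, and had no value where all samples were 0.

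The organ difference in TRB counts was 4.52 log2 units under the replicate block too, with adjusted p = 0.188, and 4.01 to 5.21 without each number, where the adjusted p was 0.0857, the unadjusted p being 0.0286, the smallest 4 numbers against 4 give. The block changed no other call. The organ comparison of V segments called 6 segments by DESeq2 and 9 with each part as its own library, 6 of 6 and 8 of 9 higher in brain. All DESeq2 calls and most of the others were joined TRAV names. With each part as its own library, TRAV7-3 was lower in brain (log2 difference -4.66) and the joined TRAV7-3/TRAV7D-3 higher (1.81). Joined names held more of the brain than of the ovary TRA counts in 5 of 5 numbers (37.9% against 30.3%). Beyond this share, whether names were assigned alike in both organs was not tested. In brain, the lead-in against the concurrent combination called 1 segment (TRAV7D-2) with no filter, 1 with each part as its own library and 0 to 2 with numbers left out (2 without number 14, where number 12 alone was left); the lead-in combination against the lead-in alone called 1 (TRAV7D-2) with no filter; and lead-in against untreated called 0 to 1 with numbers left out (1 without number 7, where number 3 alone was left). A lone number is assumed to vary like the other groups.

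Of 46 comparisons, 20 had a change under some alternative. The change was of direction, of the side of the threshold or, for the TRAV1 with TRAJ33 share, to a difference of 0. Overlap kept its direction and the smallest p its design gives under the Jaccard index, CDR3 alone, counts of 2 or more and the TRA chain. The same held with numbers left out, at 35.6% to 43.0% between organs and 23.9% to 47.6% for parts. For parts, leaving out a number also dropped the other number of its treatment, since re-pairing needs 2 numbers. The lowest value for parts was thus without numbers 12 and 14 together. The other count column was not run, since the table has 1 kind of count.

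For organ V segments, the real count was 0, which each of 100 drawn splits of the 10 libraries reaches (100 of 100) whatever the data, so the splits say nothing about chance. The highest other count was 2, 16 others gave calls, and the 11 others that part all 5 pairs gave 0.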

Other observations

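No test is reported in this part, and its items were chosen after their values were seen.

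Single alpha chain clonotypes held 4.86% or more of TRA counts in every part of both organs in numbers 12 and 3. In number 12 of the lead-in combination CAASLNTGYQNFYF (TRAV7D-2, TRAJ49) held 23.8% (95% interval 22.9% to 24.7%) and 17.6% (16.8% to 18.4%) of TRA counts in the brain parts and 29% (28.4% to 29.5%) and 30.8% (30.2% to 31.4%) in the ovary parts. It was otherwise found with 5 counts in a single brain sample, of trametinib number 13. In untreated number 3 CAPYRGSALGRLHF (TRAV7D-2, TRAJ18) held 17.0% (16.6% to 17.4%) and 14.3% (13.8% to 14.7%) of the ovary parts and 7.16% (4.73% to 10.3%) and 4.86% (2.91% to 7.58%) of the brain parts, and it was found in those 4 samples only.

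The canonical invariant natural killer T alpha chain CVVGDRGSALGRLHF with the name TRAV11N was found in 29 of 29 samples, with 6368 counts. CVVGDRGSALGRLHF with TRAV11/TRAV11D was found in 24 samples, with 1158 counts.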
